A study of Mus musculus with 2669 samples.

How the data were processed

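The series measured polyadenylated RNA in single cells dissected from the ganglionic eminences of CD1 mouse embryos, the ventral forebrain structures that give rise to cortical interneurons. The labels name the dorsal medial (dMGE), ventral medial (vMGE) and caudal (CGE) ganglionic eminence at E12.5 and E14.5. Cells were captured on Fluidigm C1 chips built for small cells, amplified with Smart-seq v4 chemistry, tagged with Nextera and read as single-end HiSeq libraries.

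Per the labels, the authors aligned and counted the reads with STAR 2.4.0 and HTSeq 0.6.1, naming CASAVA, FastQC and SAMtools beside them and the build mm9. The deposited table used here holds raw read counts per gene, 1 column per cell, which the authors made before any normalization. These counts are reads without molecular identifiers, so they are not independent molecules. A second deposited table, in RPKM, was not used here. Gene names were matched by identifier to GENCODE vM21, which gave a name to 32620 of 37310 genes; its coordinates were not used, since its build differs from the authors'. Of the genes, 6037 had no count in any cell.

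Cells needed at least 1000 detected genes and 50000 counts, which left 2650 of 2669 cells on 37 chips. Counts were scaled to 10000 per cell and put on a log scale, the 2000 most variable genes were reduced to 30 principal components, and cells were grouped with Leiden at resolution 1 on a graph of 15 neighbours. Each cluster took the name of the marker list with the highest mean difference from all cells. It needed a score of at least 0.2 and 4 markers detected in 10% of its cells, and no list of another class could lead its 10 top genes. Lists of radial glia, cycling and neurogenic intermediate progenitors were joined as progenitor-like. Clusters that met none of this stayed unnamed and entered no comparison.

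The chip is the replicate, because the labels name no animals or litters. P-values therefore measure only spread between chips, part of which may be technical. For each class, counts were summed over the cells of a chip with at least 10 such cells. This left 31 chips and 791 progenitor-like cells, with 7051117 to 50531988 counts per chip, and 30 chips and 1081 neuron-like cells, with 8121006 to 66726074. One edgeR quasi-likelihood fit per class held all 6 groups (TMM scaling, filterByExpr on the groups). The contrasts were MGE (mean of dMGE and vMGE) against CGE, vMGE against dMGE, E14.5 against E12.5 as the mean over the 3 regions, and the change of both region contrasts with age. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and levels are counts scaled to a common library size (CPM), as mean ± SD over chips.

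The 22 gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. Counts "adjusted over the list alone" correct for the list's own members. The lists covered radial glia, S phase, G2 and M phase, neurogenic intermediate progenitor, pan-neuronal, GABAergic, MGE lineage, CGE lineage, cholinergic and ventral subpallial, striatal and LGE, Hedgehog pathway, migration and guidance, early temporal, late and gliogenic, oligodendrocyte precursor, pallial excitatory, endothelial, pericyte and fibroblast, microglia, erythroid, dissociation and immediate early, and sex-linked genes. The share of neuron-like cells among named cells of a chip was compared with two-sided permutation tests, exact where a group had under 10 chips and with 100000 resamples otherwise, adjusted over 5 tests. A fold against a group at 0 was taken against a floor of 3 counts over that group, which covers counting error only.

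The groups, contrasts, tests, gene lists, markers, named-gene rule and the first set of other settings were fixed before the data were examined. Named genes are, per comparison, the 8 largest changes each way among called genes with a mean of 20 CPM or more in the higher group, predicted genes left out. Added to them are up to 4 members with the smallest adjusted p of each list that has called members, and for the MGE and CGE lists also members not called. For a change with age, the 8 genes with the smallest adjusted p and 20 CPM or more in any group are named. Details of the clustering left open in the plan were settled after marker scores and classes per chip had been seen, before any comparison of groups.

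That set held DESeq2 (Wald test, and its size factors in edgeR), no low count filter, limma on log2(mean CPM + 1) or + 10, a stricter cell filter, Leiden resolution 0.5 or 2, thinning to 50000 counts per cell, at least 5 cells per chip, all cells of a chip, no 5% of cells richest in genes, clusters without called genes, chips numbered 160 and above alone, that boundary as a covariate, and leaving out each chip. Added after the data were seen were CGE chips alone, chips below 160 alone, no chips above 4% mitochondrial counts, a covariate of median genes per cell, no cells with both Xist and Y-linked counts, scaled clustering (over all cells or within chips), 10 named cells per chip for the shares, and limma on the mean of log2(CPM + 1) over cells.

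The fit was tested on simulated counts for MGE against CGE at E12.5, with known changes put in. Real chips may differ. edgeR recovered 20.9% of genes changed 4-fold, 37.3% at 8-fold and 62.1% at 16-fold in progenitor-like cells, and 10.4%, 40.3% and 66.7% in neuron-like cells, so modest differences pass undetected at this depth and number of chips. It called 8 unchanged genes in each class, and none with nothing changed. DESeq2 called 204 and 248 unchanged genes, and limma on log2(CPM + 1) of the summed counts 13 and 3.

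Versions were Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.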

Results

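Cells of the medial ganglionic eminence (MGE), taken as a dorsal (dMGE) and a ventral (vMGE) part, and of the caudal ganglionic eminence (CGE) were sampled from CD1 mouse embryos at E12.5 and E14.5. The table held 2669 cells on 37 chips. CGE was represented by 6 chips and 468 cells at E12.5 and by 5 chips and 388 cells at E14.5. dMGE had 6 chips with 448 cells and 8 chips with 509 cells at these ages, and vMGE 7 chips with 486 cells and 5 chips with 370 cells. Counts per cell ran from 50067 to 2525162 with a median of 795688, and detected genes per cell from 662 to 6985 with a median of 3037. Summed over its cells, a chip held 71453416 to 91425033 counts in CGE at E12.5 and 58468299 to 92747163 at E14.5. The range was 35384742 to 101482176 in dMGE at E12.5 and 28255640 to 58775644 at E14.5, and 49119386 to 85061952 in vMGE at E12.5 and 37032426 to 49597743 at E14.5. Median genes per cell were 3334.5 and 3169.5 in CGE at the earlier and later age, 3834 and 2471 in dMGE, and 3438 and 2777.5 in vMGE.

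**Figure D1:**
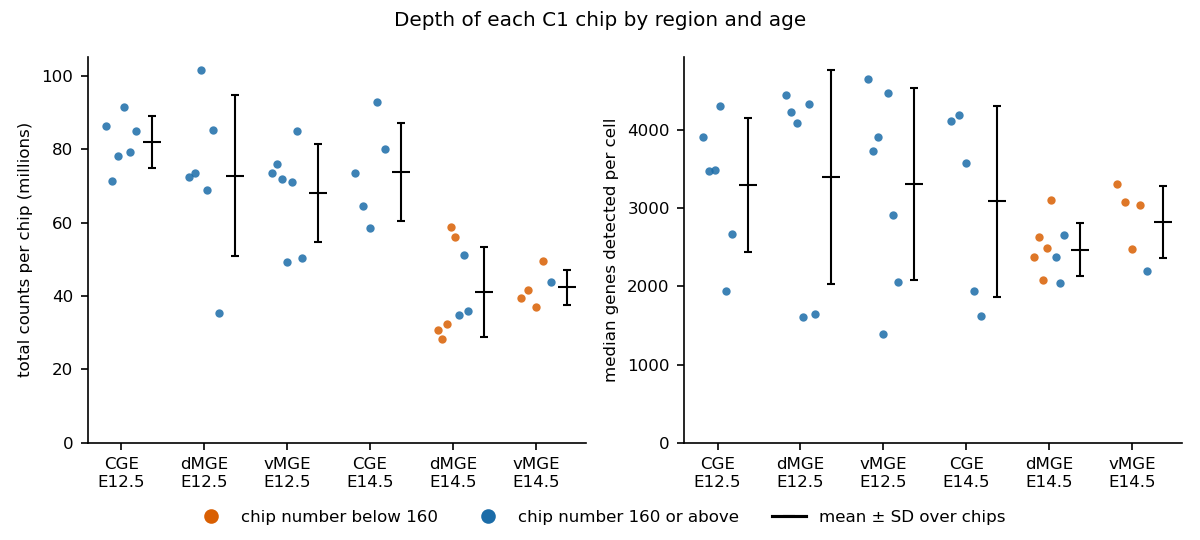
Total counts per chip and median detected genes per cell (vertical axes) for the 6 groups; each point is a chip, orange for chip numbers below 160 and blue for 160 and above, with the group mean ± SD in black. Chip totals run from 28255640 to 101482176 counts, and dMGE chips at E14.5 stay at or below 58775644.

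Chip numbers fell into separate series. All E12.5 chips and all CGE chips were numbered 160 or above, whereas most E14.5 MGE chips were numbered below 160. In the gene tests the later series held only chip 193 of dMGE and chip 194 of vMGE among the E14.5 MGE chips, so values from chips 160 and above alone are given for some genes of each E14.5 comparison. Chips 96, 97, 98 and 101 of E14.5 MGE and chip 175 of E12.5 CGE had a median mitochondrial share above 4%.

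The cells fell into 8 clusters, of which 3 were progenitor-like, 3 neuron-like and 2 unnamed. The progenitor-like clusters held 236, 335 and 238 cells, and genes of cycling cells were their best match. The neuron-like clusters held 239, 474 and 391 cells and scored highest for markers of postmitotic neurons such as Tubb3, the neuronal beta tubulin. That marker list also held genes compared below, among them Lhx6, Lhx8, Maf, Sst, Npy and Nr2f2, and the cycling list held Mki67 and Top2a. All but 4 cells of the cluster of 236 and 3 of that of 239 came from E14.5 MGE. Their leading genes include Cdk6, Nmt2, Ptp4a2, Dpysl2, GPR45, Sp8 and Plxna4. Group comparisons of both sets of genes are therefore not independent of the classes. An unnamed cluster of 183 cells had a median mitochondrial share of 9.26%. The other, of 554 cells with a median of 1813 genes, matched no list.

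The comparison of MGE with CGE at E12.5 asked which genes set these origins of interneurons apart when both produce neurons. Lhx8 (ENSMUSG00000028201), a LIM homeodomain factor of ventral subpallial and cholinergic neurons, was near absent in CGE. In progenitor-like cells it stood at 107 ± 67.2 CPM in MGE (SD, n = 11 chips) and 0.150 ± 0.243 in CGE (n = 5). In neuron-like cells it stood at 210 ± 145 (n = 9) and 0.367 ± 0.596 (n = 6). Nkx2-1 (ENSMUSG00000001496), the homeodomain factor that specifies the MGE, was higher in neuron-like cells of MGE by a log2 fold change of 3.36 ± 0.56 (SE), at 270 ± 118 CPM against 25.7 ± 13.0. These were the genes that passed the test across all genes, 1 in progenitor-like and 2 in neuron-like cells. Lhx8 had edgeR adjusted p = 0.00166 and 0.00479 in the 2 classes and was above the CGE mean on 11 of 11 and 9 of 9 MGE chips. Nkx2-1 had adjusted p = 0.00708 and was above the CGE mean on 9 of 9 MGE chips.

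Of 16 tested MGE lineage genes in progenitor-like cells, 10 had a positive fold change and 6 a negative one, with 1 called and 4 called when adjusted over the list alone (camera adjusted p = 2.75e-06, and 0.0199 with an estimated correlation). Nkx2-1 stood at 269 ± 109 CPM against 30.6 ± 31.9 and Lhx6 (ENSMUSG00000026890), which acts downstream of Nkx2-1, at 253 ± 104 against 26.9 ± 15.9. Neither passed across all genes (adjusted p = 0.233 and 0.290, each above the CGE mean on 11 of 11 chips). Of 8 CGE lineage genes, 6 were lower in MGE, 0 called and 3 adjusted over the list alone (adjusted p = 0.000145, and 0.00825 with an estimated correlation). The nuclear receptor Nr2f2 stood at 52.0 ± 41.5 CPM in MGE and 231 ± 128 in CGE, and Nr2f1 at 256 ± 210 and 700 ± 383. Cholinergic and ventral subpallial genes, which share Lhx8 with the MGE list, were positive for 9 of 10, with 1 called and 4 adjusted over the list alone (adjusted p = 1.82e-07, and 0.00825 with an estimated correlation). Pan-neuronal genes were negative for 22 of 27 (adjusted p = 0.000432, but adjusted p = 0.144 with an estimated correlation). Radial glia genes, whose median was 0.03 and mean -0.25, tested lower (adjusted p = 0.0271, but adjusted p = 0.503 with an estimated correlation), and 4 oligodendrocyte precursor genes higher (adjusted p = 0.0178, but adjusted p = 0.0944 with an estimated correlation).

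In neuron-like cells at E12.5 the list with the smallest adjusted p at the preset correlation was that of striatal and lateral ganglionic eminence genes. Of 15 tested, 12 were lower in MGE, 0 called and 5 adjusted over the list alone (adjusted p = 3.37e-09, and 0.000688 with an estimated correlation). Of 10 CGE lineage genes 9 were lower, 0 called and 1 adjusted over the list alone (adjusted p = 3.03e-07, and 0.000359 with an estimated correlation). Sp8, a zinc finger factor, stood at 0.233 ± 0.410 CPM in MGE and 52.7 ± 86.6 in CGE, and Nr2f2 at 84.6 ± 50.7 and 303 ± 211. Cholinergic genes were positive for 8 of 11, with 1 called, 5 higher and 1 lower adjusted over the list alone (adjusted p = 5.41e-06, and 0.00961 with an estimated correlation). Of 15 MGE lineage genes 7 were positive, 2 called and 4 adjusted over the list alone, with a median of -0.11, a mean of 0.76 and a test towards MGE (adjusted p = 0.0202, but adjusted p = 0.263 with an estimated correlation). Among these Lhx6 stood at 576 ± 165 CPM against 112 ± 102 and Npy, a neuropeptide of MGE interneurons, at 357 ± 199 against 80.7 ± 51.8, neither called.

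Other lists differed between MGE and CGE neuron-like cells at E12.5 only without an estimated correlation. G2 and M phase genes were positive for 24 of 25 (adjusted p = 0.000932, but adjusted p = 0.472 with an estimated correlation) and pan-neuronal genes negative for 23 of 28 (adjusted p = 0.000163, but adjusted p = 0.109 with an estimated correlation). Oligodendrocyte precursor genes were higher for 5 of 5 (adjusted p = 0.0151, but adjusted p = 0.130 with an estimated correlation) and pallial excitatory genes lower for 4 of 5 (adjusted p = 0.0202, but adjusted p = 0.109 with an estimated correlation). Dissociation and immediate early genes, a sign of handling, were positive for 8 of 10 (adjusted p = 0.00394, but adjusted p = 0.257 with an estimated correlation). Other tools called more genes at E12.5, limma 13 and DESeq2 395 in neuron-like cells, and limma 6 and DESeq2 274 in progenitor-like cells. DESeq2 also called many unchanged genes in simulated data. The 2 neuron-like calls of edgeR fell to 0 under the stricter cell filter, without the 5% of cells richest in genes, without cells holding both Xist and Y-linked counts and with either scaled clustering, where 241 to 1013 genes had an unadjusted p under 0.05.

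**Figure D2:**
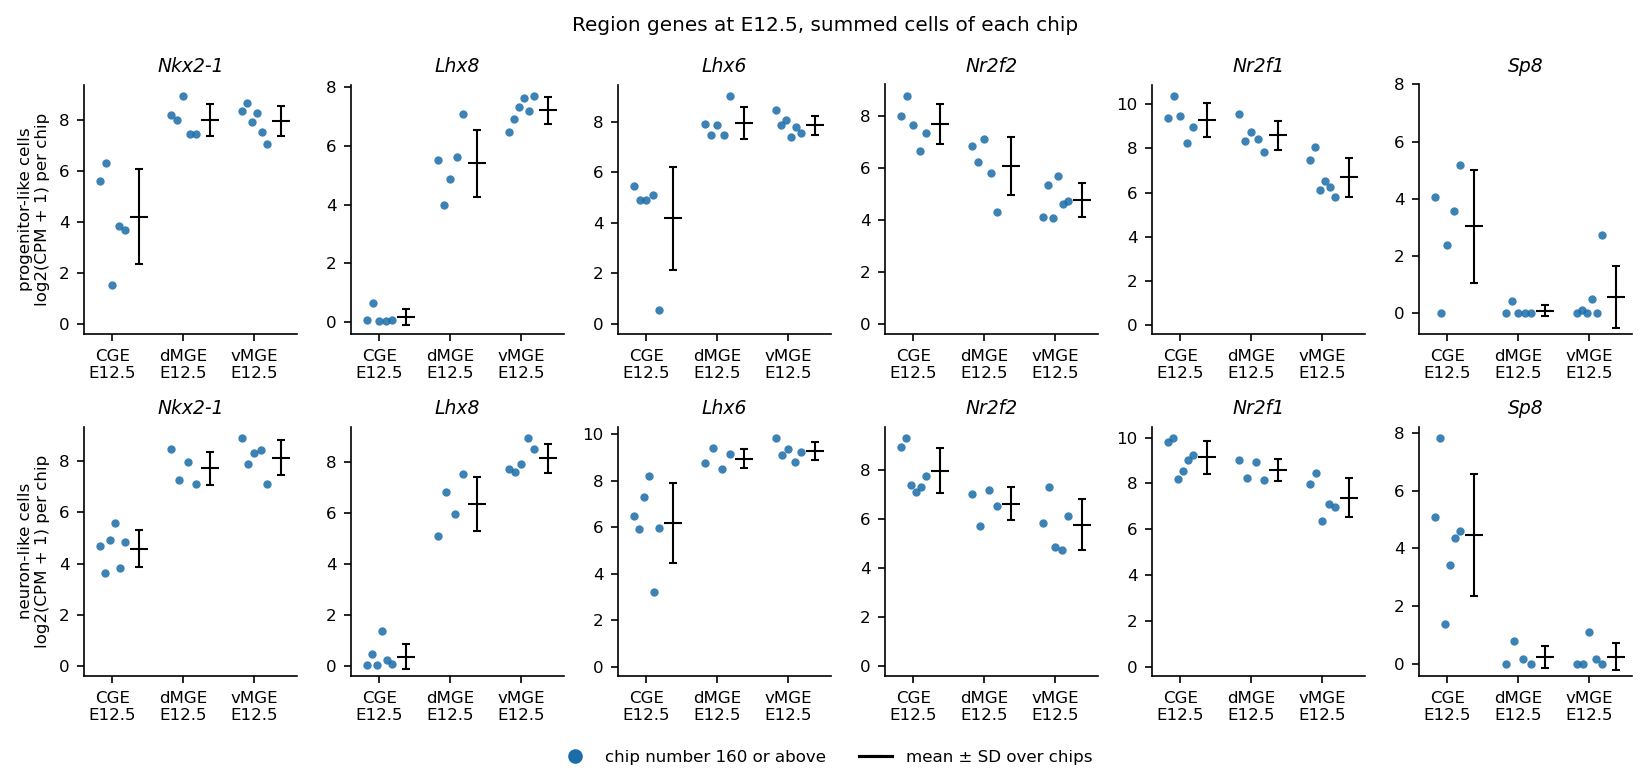
Expression of Nkx2-1, Lhx8, Lhx6, Nr2f2, Nr2f1 and Sp8 at E12.5 as log2(CPM + 1) per chip (vertical axes) in dMGE, vMGE and CGE, progenitor-like cells above and neuron-like cells below; each point is a chip, with the group mean ± SD in black. Nkx2-1 averages 269 and 270 CPM in MGE and 30.6 and 25.7 in CGE in the 2 classes.

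The comparison of vMGE with dMGE at E12.5 asked whether the parts of the MGE differ in the neurons they produce. In neuron-like cells, genes of cholinergic and ventral subpallial neurons were higher in vMGE as a group, 8 of 11 being positive, 0 called and 1 adjusted over the list alone (adjusted p = 1.16e-06, and 0.0103 with an estimated correlation). Chosen after their values were seen, Zic4 stood at 20.1 CPM in vMGE and 0.00426 in dMGE, and Zic1 at 57.6 and 8.99, both zinc finger factors of the septum and ventral forebrain. Lhx8 stood at 300 ± 126 CPM (n = 5 chips) against 97.4 ± 66.0 (n = 4), with every vMGE chip above the dMGE mean. Sst, the interneuron peptide somatostatin, averaged 1.91 CPM in vMGE and 100.3 in dMGE, with wide spread.

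Single genes of vMGE and dMGE did not pass edgeR at E12.5. It called 0 in neuron-like cells, with 725 at an unadjusted p under 0.05, 303 by DESeq2 and 0 by limma. In progenitor-like cells it called 0, with 731 at an unadjusted p under 0.05, 241 by DESeq2 and 2 by limma. In progenitor-like cells Nr2f1 averaged 122 ± 83.7 CPM in vMGE (n = 6) and 416 ± 205 in dMGE (n = 5). Nkx6-2, a homeodomain factor of the dorsal MGE, was at 0 on 6 of 6 vMGE chips and low in dMGE, at 7.97 CPM (not called). In these cells G2 and M phase genes (17 of 25, adjusted p = 0.0118) and cholinergic genes (6 of 10, adjusted p = 0.0477) tested higher in vMGE. Striatal genes (8 of 14, adjusted p = 0.0477) and endothelial genes (4 of 5, adjusted p = 0.0118) tested lower, and each of these 4 lists had adjusted p = 0.471 with an estimated correlation. In neuron-like cells pan-neuronal genes tested lower (19 of 28, adjusted p = 0.01002, but adjusted p = 0.302 with an estimated correlation). Late and gliogenic genes tested higher (10 of 13, adjusted p = 0.0222) and striatal genes lower (9 of 15, adjusted p = 0.0225), both with adjusted p = 0.246 with an estimated correlation. G2 and M phase genes tested higher (16 of 25, adjusted p = 0.0225, but adjusted p = 0.573 with an estimated correlation). Dissociation genes tested higher (8 of 10) and migration genes lower (10 of 17, median -0.46, mean 0.00), each with adjusted p = 0.0297, but adjusted p = 0.444 with an estimated correlation.

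At E14.5 the comparison of MGE with CGE asked how these regions differ once neurons accumulate. Neuron-like cells of MGE held more Nkx2-1, at 191 ± 171 CPM (n = 11 chips) against 19.98 ± 7.79 in CGE (n = 4), and Sox6, a factor of maturing MGE interneurons, at 673 ± 373 against 64.3 ± 43.0. Crabp2, which carries retinoic acid, stood at 80.9 ± 74.5 CPM against 0.384 ± 0.327, and Lhx8 at 94.2 ± 110 against 0.734 ± 1.45, its log2 fold change of 6.91 becoming 12.35 without CGE chip 162. CGE cells instead held striatal genes, with the homeodomain factor Meis2 at 579 ± 82.0 CPM against 133 ± 160 and the opioid precursor Penk at 70.0 ± 101 against 0.0199 ± 0.0547. In progenitor-like cells Lhx8 averaged 40.6 ± 54.0 CPM in MGE (n = 11) and was at 0 on 4 of 4 CGE chips, so at least 610-fold higher in MGE.

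In neuron-like cells edgeR called 160 genes, 76 higher and 84 lower in MGE, and limma on log2(mean CPM + 1) 57 higher and 126 lower. Striatal genes were lower for 12 of 15, 4 called and 6 adjusted over the list alone (adjusted p = 4.68e-09, and 0.00136 with an estimated correlation). The called members include Penk (adjusted p = 0.0149), Meis2 (0.0361) and the dopamine receptor Drd2 (0.0445). Penk and Meis2 were above the MGE mean on 4 of 4 CGE chips, Drd2 on 3. Of 15 MGE lineage genes 10 were positive, with Nkx2-1, Sox6 and Lhx8 called higher and Sst, at 3.35 ± 7.20 CPM against 235 ± 462, called lower. Adjusted over the list alone, 6 passed higher and 1 lower (adjusted p = 5.21e-05, but adjusted p = 0.0731 with an estimated correlation). Their adjusted p were 0.0168, 0.0253 and 0.0255 on 11 of 11 MGE chips. Sst, with 0.0168, was above the MGE mean on 2 of 4 CGE chips, and its log2 fold change of -10.6 became -4.84 without CGE chip 189-2. Cholinergic genes were positive for 9 of 11, 1 called and 2 adjusted over the list alone (adjusted p = 0.000837, but adjusted p = 0.0731 with an estimated correlation). Radial glia genes showed 2 called lower and no shift of the list (adjusted p = 0.742). These were Id4, an inhibitor of differentiation factors, with a log2 fold change of -3.64 ± 0.84, and the patterning factor Pax6, at 2.45 ± 2.82 CPM against 102 ± 122. Gli2, an effector of Hedgehog signalling, stood at 0.184 CPM against 30.6, the 1 called of 10 Hedgehog genes, with 3 adjusted over the list alone (camera adjusted p = 0.255, fry adjusted p = 0.00134).

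Several increases in MGE neuron-like cells at E14.5 did not recur on later numbered chips. Dpysl2 (ENSMUSG00000022048), which promotes axonal microtubule assembly, averaged 6356 ± 3753 CPM against 351 ± 404, a log2 fold change of 4.16 ± 0.80 (adjusted p = 0.0149, 9 of 11 chips), yet chips 160 and above gave -1.04. The phosphatase Ptp4a2 gave 3.83 ± 0.72 and 0.14, the septin Sept2 4.17 ± 0.78 and 0.37, superoxide dismutase Sod1 4.01 ± 0.80 and 0.59, and the orphan receptor GPR45 5.15 ± 1.04 and -0.15. Nkx2-1 gave 3.22 ± 0.65 and 2.44, Sox6 3.39 ± 0.74 and 1.75, and Crabp2 7.60 ± 1.44 and 8.15. The largest decreases were near absent in MGE. They include Rsl1, a zinc finger repressor, at 0 on 11 of 11 MGE chips and at least 1792-fold lower, the synaptic adhesion gene Igsf21, at 24.8 ± 2.52 CPM in CGE, and Cadm2, Dctd and Plpp7. Plin3, a lipid droplet protein, stood at 30.8 CPM in MGE and 0.00958 in CGE. Chips 160 and above, with 2 MGE chips, gave 2 called genes, and a chip series covariate 0. Without E14.5 CGE chip 160 the count was 0, without 161 it was 1, without 162 it was 4 and without 189-2 it was 34. Leaving out MGE chips 91, 93, 96, 98 and 99 gave 63, 54, 49, 42 and 92, and leaving out 193 and 194 gave 405 and 281.

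In progenitor-like cells at E14.5 edgeR called 43 genes, 33 higher and 10 lower in MGE, while limma on log2(mean CPM + 10) gave 145 higher and 155 lower. Lhx8 (adjusted p = 0.00330, 11 of 11 chips) was the 1 called of 16 MGE lineage genes, with 4 higher and 1 lower adjusted over the list alone and no shift of the list (adjusted p = 0.160). The other large increases again held Dpysl2, at 4.61 ± 0.82 and -0.58 on chips 160 and above, Ptp4a2 at 4.66 ± 0.79 and 0.43, and the myristoyltransferase Nmt2 at 4.71 ± 0.96 and -0.33. The imprinted gene Peg12 gave 7.08 ± 1.33 and 1.75, hexokinase Hk2 5.02 ± 1.14 and 3.07, the histone gene Hist1h4d 6.01 ± 1.27 and 3.09, and the kinase gene Mast4 9.01 ± 1.87 and 5.66. Lower in MGE were Tmem100, at 0.0544 CPM against 38.4, Cadm2, Lrrn3 and F8a. Sox6 at 190.2 CPM against 44.5 and Npy at 106 ± 89.5 against 2.18 ± 2.52 did not pass (adjusted p = 0.0761 and 0.0847, 11 of 11 chips each). Chips 160 and above gave 1 called gene, Lhx8, and a chip series covariate gave 1. Without CGE chips 160, 161, 162 and 190-2 the count was 17, 2, 3 and 19, without MGE chips 92, 93, 96 and 98 it was 11, 21, 18 and 27, and without 193 and 194 it was 244 and 207.

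Further lists passed between MGE and CGE at E14.5 at the preset correlation only. In progenitor-like cells migration and guidance genes were positive for 15 of 17, 0 called, 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.0285), and cholinergic genes for 9 of 10, 1 called and 1 adjusted over the list alone (adjusted p = 0.0417). Dissociation genes were lower for 8 of 11 (adjusted p = 0.0152). Each of these 3 had adjusted p = 0.396 with an estimated correlation. In neuron-like cells dissociation genes were lower in MGE (6 of 10, adjusted p = 0.000358) and erythroid genes, a sign of blood RNA, higher (6 of 6, adjusted p = 0.00881), each with adjusted p = 0.176 with an estimated correlation. CGE lineage genes showed no shift in either class (adjusted p = 0.965 and 0.510).

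**Figure D3:**
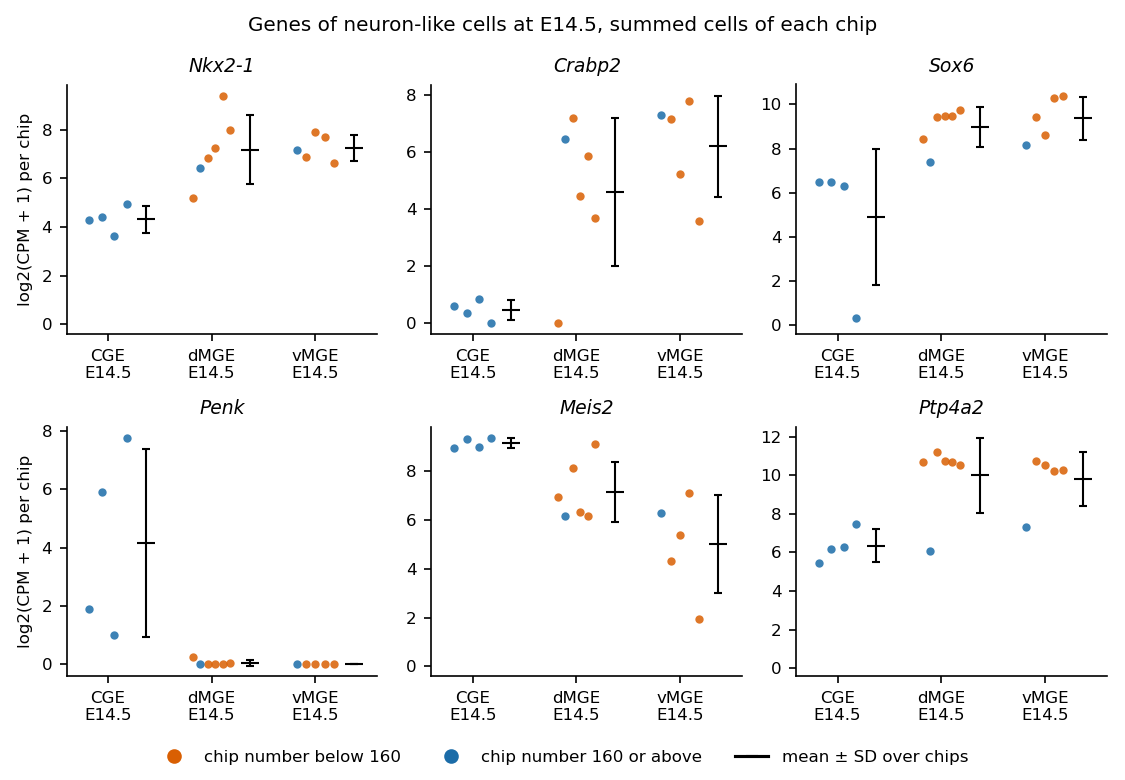
Expression of Nkx2-1, Crabp2, Sox6, Penk, Meis2 and Ptp4a2 in neuron-like cells at E14.5 as log2(CPM + 1) per chip (vertical axes) in dMGE, vMGE and CGE; points are chips, orange for chip numbers below 160 and blue for 160 and above, with the group mean ± SD in black. Ptp4a2 averages 1610 CPM on 9 early numbered MGE chips, 113 on the 2 later ones and 92.5 in CGE.

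Between vMGE and dMGE at E14.5 no gene passed edgeR in either class. In progenitor-like cells Nr2f1 averaged 34.2 ± 26.0 CPM in vMGE (n = 5 chips) and 134 ± 51.3 in dMGE (n = 6), and Lhx8 75.1 ± 66.4 and 11.8 ± 11.2. In neuron-like cells the adhesion ligand Nxph1 averaged 301 ± 201 and 88.4 ± 74.6, the MGE factor Zeb2 469 ± 300 and 980 ± 406, and the zinc finger factor St18 653 ± 199 and 350 ± 172. edgeR called 0 genes in progenitor-like cells, with 1011 at an unadjusted p under 0.05, 328 by DESeq2 and 0 by limma. In neuron-like cells it called 0, with 1533 at an unadjusted p under 0.05, 761 by DESeq2 and 4 by limma. On the chips 160 and above, 1 of each part, Nr2f1 gave -2.33 in progenitor-like cells against -1.97 over all chips. In progenitor-like cells 4 of 4 microglia genes were higher in vMGE (adjusted p = 0.00138, but adjusted p = 0.310 with an estimated correlation) and pan-neuronal genes lower for 22 of 27 (adjusted p = 0.0472, but adjusted p = 0.604 with an estimated correlation). No list differed in neuron-like cells, where the smallest adjusted p was 0.206.

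The comparison of E14.5 with E12.5, averaged over regions, asked what changes as neurogenesis proceeds. In progenitor-like cells 255 genes passed edgeR, 167 higher and 88 lower at E14.5, and in neuron-like cells 386, 279 higher and 107 lower. The balance turned with limma on log2(mean CPM + 1), at 109 higher and 412 lower and at 98 higher and 416 lower. In progenitor-like cells Nr2f1 fell, to 109 ± 74.8 CPM (n = 15 chips) from 395 ± 337 (n = 16). So did Hmga2 (ENSMUSG00000056758), a chromatin protein of young progenitors, at 4.13 ± 9.54 against 32.8 ± 55.9, and the radial glia lipid carrier Fabp7, at 415 ± 419 against 1091 ± 578. In neuron-like cells Nr2f1 fell to 118 ± 112 CPM (n = 15) from 416 ± 269 (n = 15), as did Hmga2, at 0.191 ± 0.469 against 10.0 ± 10.8, and the imprinted zinc finger gene Plagl1, at 7.84 ± 15.1 against 154 ± 166. In the order given, adjusted p was 0.00392, 0.0279 and 0.0103 in progenitor-like cells, below the E12.5 mean on 15, 14 and 13 of 15 chips. In neuron-like cells it was 0.0340, 0.0188 and 0.00395, on 14, 15 and 15 chips. These kept their direction on chips 160 and above, where Nr2f1 gave -1.86 and -1.28, Hmga2 -8.61 and -5.31, Fabp7 -1.82 and Plagl1 -4.67, and in CGE chips alone, an alternative added after the data were seen.

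The increases with age in progenitor-like cells include single genes of division and of neurons. Top2a (ENSMUSG00000020914), a topoisomerase of dividing cells, rose by a log2 fold change of 1.65 ± 0.26 (adjusted p = 0.00189, above the E12.5 mean on 14 of 15 chips) and Mki67 by 1.16 ± 0.29 (0.0297, 10 chips). They were the 2 called of 25 G2 and M phase genes, of which 19 were positive and 6 passed adjusted over the list alone (camera adjusted p = 0.0630). Of 27 pan-neuronal genes 20 were positive, 5 called higher, and 9 higher and 1 lower adjusted over the list alone (adjusted p = 0.00452, but adjusted p = 0.348 with an estimated correlation). Among them Tubb3 (ENSMUSG00000062380) gave 1.60 ± 0.32 and Dcx, which stabilises microtubules of migrating neurons, 1.64 ± 0.33. Early temporal genes were negative for 6 of 7, with 1 called, Hmga2, and 2 adjusted over the list alone (adjusted p = 0.00979, but adjusted p = 0.312 with an estimated correlation). Late and gliogenic genes were positive for 9 of 13, with Nfia, a factor of the switch to glia, called higher at 1.65 ± 0.35 and Hopx called lower. Adjusted over the list alone, 6 passed higher and 1 lower (adjusted p = 0.0248, but adjusted p = 0.410 with an estimated correlation). Of 22 radial glia genes 14 were negative, 1 called, Fabp7, and 7 lower and 1 higher adjusted over the list alone (adjusted p = 0.0462, but adjusted p = 0.702 with an estimated correlation). Of 14 neurogenic intermediate progenitor genes 10 were negative, with the cell cycle gene Ccnd2 called higher at 1.47 ± 0.24 and the stress gene Gadd45g called lower at -2.10 ± 0.46. Adjusted over the list alone, 1 passed higher and 4 lower (adjusted p = 0.278). Microglia genes tested higher for 3 of 4 (adjusted p = 0.00979, but adjusted p = 0.348 with an estimated correlation) and dissociation genes lower for 6 of 11 (adjusted p = 0.0108, but adjusted p = 0.410 with an estimated correlation). S phase genes showed no shift (adjusted p = 0.608).

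The age increases of progenitor-like cells were smaller on later numbered chips, and some turned. Top2a gave 0.40, Mki67 -0.33, Tubb3 -0.16, Nfia -0.43, Ccnd2 0.22 and Dcx 0.98 on chips 160 and above. Igf1r, the growth factor receptor, gave 3.46 ± 0.73 and 1.02, and Cdk6, a kinase of the G1 phase, 3.68 ± 0.72 and -0.89. Among the largest decreases were Plk3, Rbfa, the Wnt antagonist Sfrp4, Spry1, a brake on growth factor signalling, Lipt2, Siah2 and Spin2c. Chips 160 and above gave 1 called gene, a chip series covariate 0, and CGE chips alone 0 by edgeR, with 262 at an unadjusted p under 0.05. Without chips above 4% mitochondrial counts the count was 37, and without cells holding both Xist and Y-linked counts it was 22. Leaving out E14.5 CGE chips 160, 161 and 162 gave 169, 144 and 152 genes, leaving out E12.5 dMGE chip 184 gave 161, and leaving out E14.5 MGE chips 193 and 194 gave 560 and 525.

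The increases with age in neuron-like cells include Ncam1, Tubb3 and Maf. Of 28 pan-neuronal genes 20 were positive, 8 called and 10 adjusted over the list alone (adjusted p = 0.00149, but adjusted p = 0.162 with an estimated correlation). The adhesion molecule Ncam1 rose by 1.55 ± 0.27 (adjusted p = 0.00208, 13 of 15 chips), the synaptic gene Nrxn3 by 1.54 ± 0.28, Tubb3 by 1.56 ± 0.31 and Map1b by 0.90 ± 0.17. Of 15 MGE lineage genes 12 were positive, 5 called higher, and 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.00451, but adjusted p = 0.162 with an estimated correlation). Among them were the interneuron factor Maf at 2.44 ± 0.50, Zeb2 at 1.59 ± 0.38, Lhx6 at 1.20 ± 0.32 and Npy at 1.20 ± 0.31. Of 17 migration genes 15 were positive, with the semaphorin receptor Plxna4 called higher at 2.72 ± 0.55 and Nrp2 called lower, from 16.8 ± 13.9 to 2.03 ± 2.73 CPM. Adjusted over the list alone, 6 passed higher and 1 lower (adjusted p = 0.00176, but adjusted p = 0.162 with an estimated correlation). Late and gliogenic genes were positive for 9 of 13, 3 called and 6 adjusted over the list alone (adjusted p = 0.00556, but adjusted p = 0.162 with an estimated correlation), with Nfib at 1.39 ± 0.28 and Zbtb20 at 1.19 ± 0.28. Intermediate progenitor genes were negative for 11 of 14 and early temporal genes for 6 of 7 (adjusted p = 0.0155 each), while 3 of 3 pericyte genes were positive, Pdgfrb called (adjusted p = 0.0219). These 3 lists had adjusted p = 0.162 with an estimated correlation.

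G2 and M phase genes were negative for 24 of 25 in neuron-like cells at E14.5, 1 called, the chromatin protein Hmgb2, and 3 adjusted over the list alone (adjusted p = 7.16e-08, but adjusted p = 0.173 with an estimated correlation). Radial glia genes were negative for 15 of 22 (adjusted p = 0.0242) and striatal genes positive for 11 of 15, with Meis1 called (adjusted p = 0.0310), both with adjusted p = 0.198 with an estimated correlation. Dissociation genes were lower for 6 of 10 (adjusted p = 0.00828, but adjusted p = 0.215 with an estimated correlation). The GABAergic list did not shift (adjusted p = 0.703), though Dlx2, a factor of subpallial progenitors, fell by 1.21 ± 0.29, 1 called and 2 adjusted over the list alone. CGE lineage genes did not shift either (adjusted p = 0.703, median -0.46, mean 0.55), with Sp8 called higher and Nr2f1 lower. Hbb-y, an embryonic globin, was called lower, at 2.56 CPM against 21.2, within an erythroid list that did not shift (adjusted p = 0.410). The remaining lists had adjusted p = 0.468 for S phase, 0.507 for endothelial and for oligodendrocyte precursor, 0.412 for sex-linked, 0.0928 for pallial excitatory, 0.280 for microglia, 0.410 for Hedgehog and 0.276 for cholinergic genes.

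On chips 160 and above the age changes of neuron-like cells were 0.17 for Ncam1, 0.16 for Nrxn3, -0.56 for Tubb3, 0.38 for Map1b, 0.06 for Maf, 0.22 for Zeb2, 0.45 for Lhx6, 0.63 for Npy, 1.09 for Plxna4, 0.34 for Nfib and -1.02 for Dlx2. CGE chips alone gave 0.83 for Ncam1, 1.72 for Maf, 1.58 for Zeb2, 1.41 for Lhx6, 1.82 for Npy, 2.50 for Plxna4, 1.31 for Nfib and 0.06 for Dlx2. The largest increases, Sp8, Unc5d, Pou4f1, Nos1, Itga9, Crebl2, Rn7sk and Tgfb3, included Sp8 at 195 ± 278 CPM against 21.2 ± 58.2. Chips 160 and above gave -1.41 for Sp8, -4.36 for Unc5d, -2.51 for Pou4f1, -0.775 for Itga9, -0.81 for Crebl2 and -0.043 for Rn7sk, and Nos1 went from 6.76 to 3.73 without chip 97. Chips 160 and above and a chip series covariate gave 0 called genes each, as did CGE chips alone by edgeR, with 324 at an unadjusted p under 0.05, and without chips above 4% mitochondrial counts the count was 110. Leaving out E14.5 CGE chips 160, 161 and 162 gave 245, 208 and 202 genes, E12.5 dMGE chips 170, 173, 176 and 184 gave 190, 162, 171 and 170, and E14.5 MGE chips 193 and 194 gave 719 and 707.

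**Figure D4:**
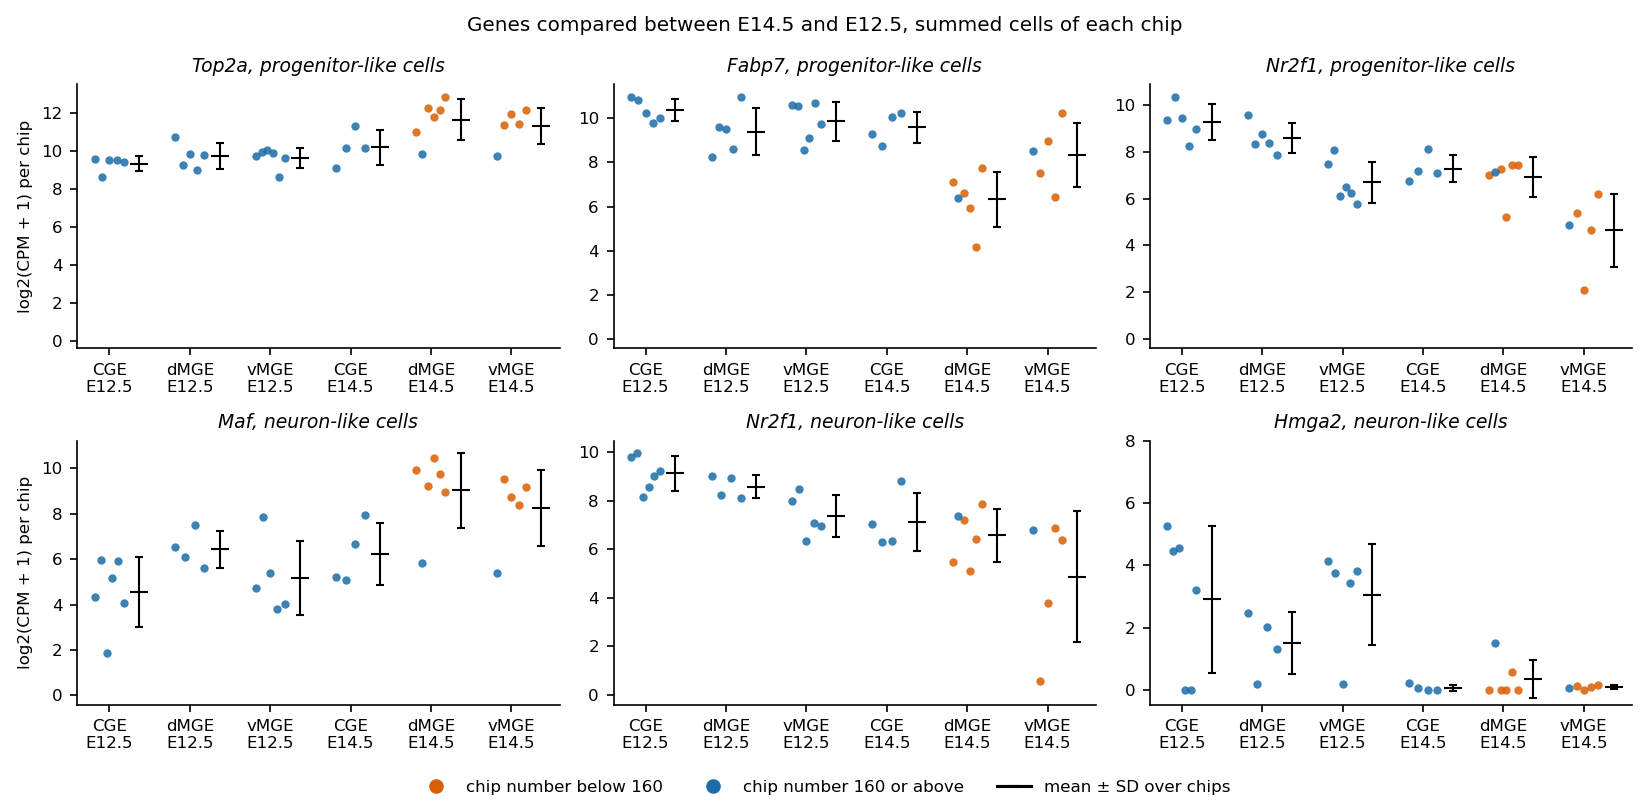
Expression as log2(CPM + 1) per chip (vertical axes) of Top2a, Fabp7 and Nr2f1 in progenitor-like cells and of Maf, Nr2f1 and Hmga2 in neuron-like cells in the 6 groups; points are chips, orange for chip numbers below 160 and blue for 160 and above, with the group mean ± SD in black. Maf averages 714 CPM on 9 early numbered E14.5 MGE chips and 48.2 on the 2 later ones, while Nr2f1 averages 118 CPM over all E14.5 chips and 416 over E12.5 chips.

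Whether the region contrasts changed with age was tested directly. No gene passed for MGE against CGE. The nearest in progenitor-like cells were Ptp4a2 at 4.88 ± 0.89, Dpysl2 at 4.86 ± 0.93 and Hist1h4d at 7.54 ± 1.47, each with adjusted p = 0.0554. In neuron-like cells they were Sept2, Ptp4a2, Tet2, Rpl3, Dpysl2, Sod1 and Rps4x with positive values and Sox4, a factor of newborn neurons, at -2.69 ± 0.53, each with adjusted p = 0.0604. On chips 160 and above Ptp4a2 gave 0.64 and 0.73, Dpysl2 -0.34 and -0.69, and Sox4 -2.31. For vMGE against dMGE the smallest adjusted p was 0.302 in progenitor-like and 0.296 in neuron-like cells. In progenitor-like cells edgeR called 0 genes for MGE against CGE, with 1533 at an unadjusted p under 0.05, 783 by DESeq2 and 2 by limma, and 0 for vMGE against dMGE, with 880, 303 and 0. In neuron-like cells these were 0 genes, with 1494, 664 and 1, and 0 genes, with 1105, 576 and 1. In the first, limma on the mean of log2(CPM + 1) over cells called 12 higher and 1334 lower. Without E14.5 MGE chip 193 the MGE against CGE counts were 35 and 86, and without 194 they were 11 and 76.

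Among the lists, dissociation genes showed the smallest adjusted p for a change of the MGE and CGE contrast with age. The contrast was lower at E14.5 for 8 of 11 in progenitor-like cells (adjusted p = 0.00258, but adjusted p = 0.537 with an estimated correlation). It was lower for 10 of 10 in neuron-like cells (adjusted p = 3.19e-06, but adjusted p = 0.223 with an estimated correlation). In neuron-like cells G2 and M phase genes were lower for 22 of 25 (adjusted p = 0.00279, but adjusted p = 0.661 with an estimated correlation). Pan-neuronal genes were higher for 25 of 28 (adjusted p = 0.0105) and erythroid genes for 6 of 6 (adjusted p = 0.0478), both with adjusted p = 0.340 with an estimated correlation. For vMGE against dMGE, microglia genes were higher for 4 of 4 in progenitor-like cells (adjusted p = 0.00128, but adjusted p = 0.369 with an estimated correlation). Pericyte genes were lower for 3 of 3 in neuron-like cells (adjusted p = 0.0474, but adjusted p = 0.538 with an estimated correlation).

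From 0 (chip 171) to all 49 (chip 180) cells of a chip stayed unnamed, 22.55 to 36.65% per group. The neuron-like share of named cells may thus reflect gene detection. It averaged 62.0% ± 18.9 (SD, n = 17 chips) at E14.5 and 51.2% ± 20.6 (n = 18) at E12.5, 10.8 points higher, within the spread between chips (two-sided permutation p = 0.115, adjusted p = 0.415). MGE lay 11.8 points below CGE at E12.5, at 47.3% ± 21.4 (n = 12) against 59.1% ± 18.1 (n = 6, exact permutation p = 0.263). It lay 10.1 below at E14.5, at 59.1% ± 18.4 (n = 12) against 69.2% ± 20.04 (n = 5, exact permutation p = 0.332). vMGE stood at 51.0% ± 17.5 (n = 6) and dMGE at 43.6% ± 25.9 (n = 6) at E12.5 (exact permutation p = 0.595). At E14.5 they stood at 51.0% ± 14.7 (n = 5) and 64.9% ± 19.7 (n = 7, exact permutation p = 0.207). Each vMGE chip then lay below its neighbouring dMGE chips, a pairing not tested. On chips 160 and above the age difference was 20.3 points and that of MGE and CGE at E14.5 6.25 points, while vMGE and dMGE at E14.5 differed by -7.63 points on chips below 160. Without E12.5 dMGE chip 181 (0 neuron-like of 6 named cells) vMGE was -1.36 points from dMGE, and without E14.5 dMGE chip 191 (1 named cell) -8.01. The age difference passed its test without the 5% of cells richest in genes, at 22.0 points, and with finer clusters, at 22.9 points. It was 5.43 points with 10 or more named cells per chip and 4.25 with clusters scaled within chips.

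**Figure D5:**
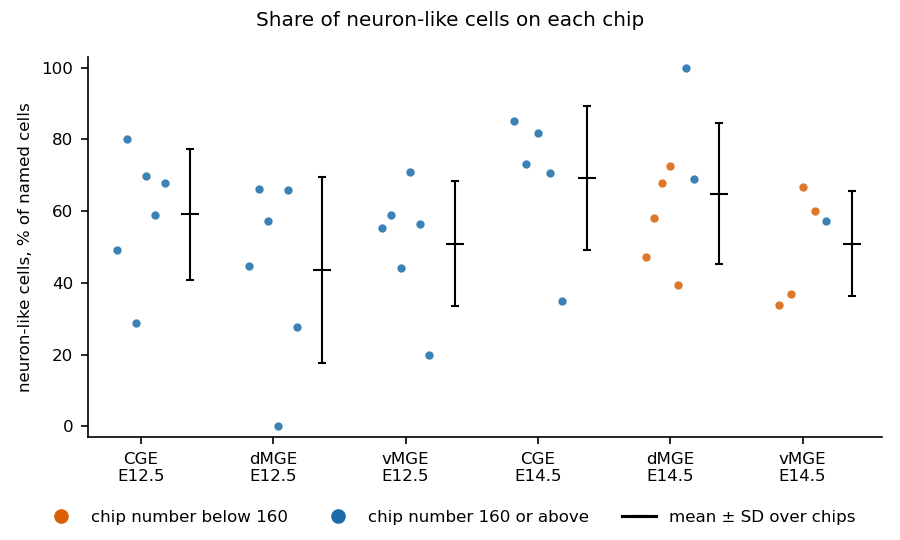
Share of neuron-like cells in % of named cells (vertical axis) for the 6 groups; each point is a chip, orange for chip numbers below 160 and blue for 160 and above, with the group mean ± SD in black. Group means lie between 43.6% in dMGE at E12.5 and 69.2% in CGE at E14.5, with wide overlap of chips.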

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

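A value was marked when 1 chip of a group lay far from the rest, its gap to the nearest other chip, over the range of the group, passing Dixon's 95% limit. Chance marks about 1 in 20 groups of normally distributed values. Of 598 groups 107 were marked, 106 of 568 gene levels, 1 of 24 depth values and 0 of 6 shares. The gene levels were those of called genes, often near absent in a group, so that rate does not hold for them. A ratio of 1 arises at any level when all other chips are equal. Cadm2 in progenitor-like dMGE cells at E14.5 had log2(CPM + 1) of 0.0611 on chip 101 and 0 on the others. Chips 193 and 194, the late numbered chips of E14.5 MGE, hold 20 and 14 of the gene marks and chip 93 holds 6. The median mitochondrial share of E12.5 CGE chip 175 was 5.36% against 0.815 to 2.24% on the others, a ratio of 0.687. The ratios of gene levels follow, above or below the other chips of the group.

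Progenitor-like cells of CGE at E12.5 had chip 179 above in Cdc42bpb (0.813), chip 172 above in Dpysl3 (0.742), chip 187 below in F8a (0.754) and Zfp367 (0.777), chip 182 above in Ikzf1 (0.895), chip 175 above in Lhx8 (0.903), chip 175 below in Top2a (0.825). vMGE at E12.5 had chip 185 below in Mki67 (0.661) and Top2a (0.698), chip 196 below in Mmd2 (0.673), chip 171 below in Spry1 (0.650). CGE at E14.5 had chip 162 above in Hmga2 (1), chip 161 above in Lipt2 (0.961) and Spry1 (1). dMGE at E14.5 had chip 101 above in Cadm2 (1), chip 193 below in Dpysl2 (0.790), GPR45 (0.672), Mki67 (0.631), Nfia (0.666), Peg12 (0.685) and Ptp4a2 (0.780), chip 90 above in Hopx (1) and Ikzf1 (1), chip 92 below in Nr2f1 (0.796), chip 193 above in Plk3 (0.911), Sfrp4 (0.842) and Spry1 (1), chip 92 above in Rbfa (0.760), chip 99 above in Tmem100 (1). vMGE at E14.5 had chip 93 above in Cadm2 (0.925), Lipt2 (0.751), Lrrn3 (1), Plk3 (0.722) and Rbfa (1), chip 194 below in Hist1h4d (0.762), Nfia (0.780), Nmt2 (0.734), Ptp4a2 (0.835) and Tubb3 (0.799), chip 91 above in Hmga2 (0.932), chip 194 above in Spry1 (0.85).

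Neuron-like cells of CGE at E12.5 had chip 186 below in Crabp2 (0.769) and Id4 (0.801), chip 172 above in Crebl2 (0.857) and Tnc (0.926), chip 182 above in Itga9 (1), Lhx8 (0.680), Penk (0.645) and Plin3 (0.923), chip 175 above in Pdgfrb (1), chip 179 above in Pou4f1 (1). dMGE at E12.5 had chip 173 above in Dctd (0.910) and Pax6 (0.867), chip 176 above in Drd2 (1) and Nos1 (1), chip 170 above in Plpp7 (1) and Pou4f1 (0.989), chip 184 above in Unc5d (0.932). vMGE at E12.5 had chip 183 above in Cadm2 (0.986) and Drd2 (0.978), chip 177 below in Hmga2 (0.820), chip 174 above in Itga9 (1), chip 185 below in Meis1 (0.853) and Sapcd2 (0.777), chip 177 above in Sp8 (0.849), chip 185 above in Tnc (1). CGE at E14.5 had chip 189-2 above in Dpysl2 (0.873), chip 162 above in Itga9 (1), Lhx8 (0.986) and Pou4f1 (0.955), chip 160 above in Nos1 (0.951), chip 161 above in Plin3 (1), chip 189-2 below in Sox6 (0.970) and Tubb3 (0.857). dMGE at E14.5 had chip 97 above in Dctd (1) and Nos1 (0.983), chip 193 below in Dpysl2 (0.830), GPR45 (0.879), Maf (0.674), Ncam1 (0.764), Nrxn3 (0.674), Ptp4a2 (0.871), Sept2 (0.836), Sod1 (0.851) and Zeb2 (0.832), chip 90 above in Drd2 (1), Hbb-y (0.817) and Plpp7 (0.900), chip 193 above in Fez2 (1) and Gli2 (0.919), chip 101 above in Igsf21 (1) and Penk (0.777), chip 99 above in Nrp2 (1). vMGE at E14.5 had chip 98 above in Cadm2 (1) and Tnc (1), chip 194 below in Dpysl2 (0.792), GPR45 (0.776), Maf (0.717), Ncam1 (0.849), Nrxn3 (0.818), Ptp4a2 (0.851) and Tubb3 (0.810), chip 194 above in Edil3 (1), chip 93 above in Fez2 (0.739), chip 91 above in Itga9 (0.899), chip 96 above in Pdgfrb (0.716).

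The tests below were set down before their results. Pattern 1 is the E14.5 against E12.5 calls, 255 genes in progenitor-like and 386 in neuron-like cells, where E14.5 MGE chips were mostly numbered below 160. Genes called on a first part of the MGE chips, 208 and 268, differed in held-out MGE chips by 4.75 and 4.39 in log2, while the CGE chips, all late numbered, showed 5.64% and 1.64% of that (exact permutation p = 0.27 and 0.89). Late numbered E14.5 MGE chips 193 and 194 showed -8.79% (-11.5 to -6.07) and -2.62% (-9.48 to 4.24). The chip series thus has the values it needs for these genes as a set. In CGE chips alone, neuron-like cells gave 1.58 for Zeb2, 1.41 for Lhx6 and 1.82 for Npy, none called. On chips 160 and above these were smaller, so they stay open. Chips rich in mitochondrial counts are excluded as the cause, since without 5 such chips the fold changes of called genes were 0.971 and 0.964 times the full ones (median absolute value 2.52 to 2.45 and 2.44 to 2.23, standard error 0.607 to 0.633 and 0.558 to 0.57), though 36 and 94 stayed called with fewer chips. Those values on chips 193 and 194 argue against an age change in every E14.5 MGE chip as the whole of these differences, while a smaller one, or one in other genes, stays open.

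Pattern 2 is the MGE against CGE calls at E14.5, 43 and 160 genes. In neuron-like cells 14 genes, 13 of them higher in MGE, were called on a first part of the early numbered MGE chips and of the CGE chips. They differed by 6.31 in held-out early numbered MGE chips, and chips 193 and 194 showed 10.2% of that (8.8 to 11.5). The chip series therefore has the value it needs for these genes. In progenitor-like cells that part called 8 genes, too few to read, so the chip series and region cannot be told apart there. Chips rich in mitochondrial counts are excluded again, at ratios of 0.960 and 0.979 (median absolute value 3.15 to 3.01 and 4.16 to 4.04, standard error 0.675 to 0.662 and 0.892 to 0.985), with 4 and 3 genes still called on fewer chips. The 10.2% also argues against a difference between regions as the whole of it for those 14 genes, while Crabp2 and Nkx2-1 gave 8.15 and 2.44 on chips 160 and above (7.60 and 3.22 over all chips), so the series is not their whole cause, and the genes lower in MGE stay open.

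Pattern 3 is the 626 cells, 23.6% of 2650, with both Xist and Y-linked counts. The lower of the levels had a median of 0.0564 of that in cells of the same chip with 1 kind alone. Its upper quartile was 0.610, with 55.75% of cells under 0.1 and 35.3% at 0.25 or more. Carry-over of RNA or reads between cells has the value it needs. The 0.0564 cannot exclude 2 cells in 1 capture site, as the spread in cells with 1 kind alone was not compared. The 3870 median genes of the 626 cells, against 3025 with Xist alone and 3224 with Y alone, go the way of 2 cells. No biological explanation was tested.

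Chance was tested by regrouping the same chips 100 times, the real grouping included. The real grouping alone (1 of 100) gave as many genes for MGE against CGE at E12.5 in progenitor-like cells (1, highest other 0) and neuron-like cells (2, highest other 1), at E14.5 (43, highest other 6, and 160, highest other 22), and for E14.5 against E12.5 (255, highest other 1, and 386, highest other 2). As 1 of 100 is the smallest share this test can give, chance is unlikely for these 6 but not excluded. The regroupings ignore the chip series, so for the E14.5 and age results they do not part region or age from it. For the 8 results where edgeR called 0, all 100 groupings give as many by construction, which decides nothing about chance. Their highest other was 0 at E12.5 in both classes and 9 and 10 at E14.5 for vMGE against dMGE, 0 and 3 for the age difference of MGE against CGE, and 46 and 2 for that of vMGE against dMGE.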

How the results depend on the processing

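Counts of called genes, shares, signs of genes and directions of lists were recomputed under each alternative. The alternatives added after the data were seen are CGE chips alone, chips below 160, no chips above 4% mitochondrial counts, the median of genes detected as a covariate, no cells holding both Xist and Y-linked counts, clusters from scaled values and from values scaled within chips, 10 named cells per chip, and limma on the mean of log2(CPM + 1) over cells. Of the counts 159 were within 1.5 times the main count and 125 moved further. Of gene values 2785 kept direction and side of the threshold, 948 kept direction and no longer passed, 147 kept direction and newly passed, and 132 turned. Of list results 661 were the same, 254 weaker and 45 turned, and of shares 45 were the same, 4 newly passed and 12 turned. RLE in place of TMM moved no count and turned no gene. Below, gene values are log2 fold changes, with 0 where neither group held a count, list values are camera adjusted p in the turned direction, share values are percentage points, with age means E14.5 against E12.5, and MGE/CGE and vMGE/dMGE mean the first against the second. Where no cause is named, the cause was not tested.

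The labels give no replicate number, litter or animal shared between regions, and neighbouring chip numbers were not tried as blocks, for genes or shares. The share of vMGE/dMGE at E14.5 has no value on chips 160 and above, where vMGE has a single chip. A lone chip in a fit of genes is assumed to vary like the chips of the other groups. Thinning each cell to 50000 counts moved 6 counts, each of them upward, and turned no gene and no list.

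Without a low count filter counts in progenitor-like cells were for MGE/CGE 355 at E12.5 (4 higher, 351 lower), 12 at E14.5 and 2 in its age difference. Neuron-like cells had, in turn, for MGE/CGE 53 at E14.5 and 3 in its age difference. List adjusted p in progenitor-like cells was 0.838 (pan-neuronal) and 0.859 (late and gliogenic) with age. Turned lists of neuron-like cells had adjusted p = 0.857 (pan-neuronal) for MGE/CGE at E12.5, 0.751 (pan-neuronal) and 0.892 (MGE lineage) with age and 0.237 (pan-neuronal) for the age difference of MGE/CGE. By the DESeq2 Wald test counts in progenitor-like cells were for MGE/CGE 274 at E12.5, 1325 at E14.5 and 783 in its age difference, for vMGE/dMGE 241 at E12.5, 328 at E14.5 and 303 in its age difference and 1302 with age. The other class, neuron-like cells, had for MGE/CGE 395 at E12.5, 977 at E14.5 and 664 in its age difference, for vMGE/dMGE 303 at E12.5, 761 at E14.5 and 576 in its age difference and 1448 with age. By limma on log2(mean CPM + 1) counts in progenitor-like cells were for MGE/CGE 6 at E12.5, 233 at E14.5 and 2 in its age difference, for vMGE/dMGE 2 at E12.5 and 521 with age. Counts in neuron-like cells were for MGE/CGE 13 at E12.5 and 1 in its age difference and for vMGE/dMGE 4 at E14.5 and 1 in its age difference. In progenitor-like cells signs turned for Htr3a 0.050 for MGE/CGE at E14.5. By limma on log2(mean CPM + 10) counts in progenitor-like cells were for MGE/CGE 8 at E12.5, 300 at E14.5 and 1 in its age difference, for vMGE/dMGE 1 at E12.5 and 614 with age. Those of neuron-like cells were for MGE/CGE 5 at E12.5, 241 at E14.5 and 6 in its age difference, for vMGE/dMGE 1 at E14.5 and 1 in its age difference and 606 with age. Signs turned in progenitor-like cells for Htr3a 0.014 for MGE/CGE at E14.5. By limma on the mean of log2(CPM + 1) over cells counts in progenitor-like cells were for MGE/CGE 21 at E12.5, 1257 at E14.5 and 2 in its age difference and 571 with age. Neuron-like cells had, in turn, for MGE/CGE 45 at E12.5, 1785 at E14.5 and 1346 in its age difference, for vMGE/dMGE 3 at E12.5 and 1 at E14.5 and 2423 with age. Most of its E14.5 and age calls were lower, with 144 higher and 1113 lower in progenitor-like MGE and 107 higher and 1678 lower in neuron-like MGE, and with age 147 higher and 424 lower and 204 higher and 2219 lower.

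With cells thinned to 50000 counts counts in progenitor-like cells were for MGE/CGE 2 at E12.5, 165 at E14.5 and 6 in its age difference. The other class, neuron-like cells, had for MGE/CGE 8 at E12.5 and 2 in its age difference and for vMGE/dMGE 1 at E14.5. With the median of genes detected as a covariate counts in progenitor-like cells were for MGE/CGE 108 at E14.5 and 10 in its age difference and 870 with age. Counts in neuron-like cells were for MGE/CGE 98 at E14.5 and 3 in its age difference. With 5 cells per chip as the minimum counts in progenitor-like cells were for MGE/CGE 22 at E14.5 and 1 in its age difference. Turned genes of progenitor-like cells were Htr3a -2.72 for vMGE/dMGE at E12.5 and Npy 0.060 with age. Under the stricter cell filter counts in progenitor-like cells were for MGE/CGE 4 at E12.5 and 10 at E14.5. Those of neuron-like cells were for MGE/CGE 0 at E12.5, 52 at E14.5 and 2 in its age difference and 28 with age. The neuron-like share gave -14.7 points for vMGE/dMGE at E12.5. Reversed genes in progenitor-like cells were Nr2f2 0.38 for vMGE/dMGE at E14.5. In neuron-like cells signs turned for Calb2 0 for MGE/CGE at E12.5 and Calb2 0 for vMGE/dMGE at E12.5. Without the 5% of cells with most genes counts in progenitor-like cells were for MGE/CGE 28 at E14.5. Neuron-like cells had, in turn, for MGE/CGE 0 at E12.5, 9 at E14.5 and 2 in its age difference, for vMGE/dMGE 1 at E14.5 and 132 with age. The share of neuron-like cells gave 22.04 points for E14.5 against E12.5 (past the threshold) and -6.18 points for vMGE/dMGE at E12.5. Signs turned in neuron-like cells for Calb2 4.26 for MGE/CGE at E12.5 and Rgs5 2.08 and Abcc9 0.86 for the age difference of vMGE/dMGE.

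Without cells holding Xist and Y-linked counts counts in progenitor-like cells were for MGE/CGE 3 at E12.5 and 1 at E14.5 and 22 with age. The other class, neuron-like cells, had for MGE/CGE 0 at E12.5. Turned genes of progenitor-like cells were Htr3a 5.75 and Nkx6-2 0 for MGE/CGE at E14.5 and Npas1 0 and Nkx6-2 0 for vMGE/dMGE at E14.5. Without chips above 4% mitochondrial counts counts in progenitor-like cells were for MGE/CGE 4 at E14.5 and 37 with age. Counts in neuron-like cells were for MGE/CGE 4 at E14.5 and 110 with age. Reversed genes in progenitor-like cells were Nkx6-2 0 for vMGE/dMGE at E14.5. In CGE chips alone counts in progenitor-like cells were 0 with age. The other class, neuron-like cells, had 0 with age. In progenitor-like cells signs turned for Cdc42bpb -0.66, Mki67 -0.32, Zcwpw1 -0.039 and Sp8 -0.404 with age. Signs turned in neuron-like cells for Dlx2 0.063 and Sp8 -0.055 with age. Fewer chips enter here by construction.

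With the chip series as a covariate counts in progenitor-like cells were for MGE/CGE 1 at E14.5 and 0 with age. Those of neuron-like cells were for MGE/CGE 4 at E12.5 and 0 at E14.5 and 0 with age. In progenitor-like cells signs turned for Npas3 -0.55 and Dpysl2 -0.57 for MGE/CGE at E14.5, Cdc42bpb -0.72, Nfia -0.43, Mki67 -0.34, Mmd2 -4.36, Cux2 -0.89, Zfp367 -0.58, Sp8 -2.08, Tubb3 -0.14, GPR45 -0.28 and AC113316.1 -1.14 with age and Dpysl2 -0.32 and Mn1 -0.075 for the age difference of MGE/CGE. Signs turned in neuron-like cells for Dpysl2 -0.94 and GPR45 -0.092 for MGE/CGE at E14.5, Tnc -0.043, Crebl2 -0.81, Itga9 -2.79, Pou4f1 -2.38, Tubb3 -0.37, Unc5d -4.17 and Rn7sk -0.036 with age and Dpysl2 -0.57 for the age difference of MGE/CGE. For lists in progenitor-like cells adjusted p was 0.0993 (dissociation) for MGE/CGE at E14.5, 0.923 (late and gliogenic) and 0.187 (dissociation) with age and 0.455 (dissociation) for the age difference of MGE/CGE. List adjusted p in neuron-like cells was 0.907 (dissociation) for MGE/CGE at E14.5, 0.396 (dissociation) with age and 0.881 (G2 and M phase) and 0.955 (pan-neuronal) for the age difference of MGE/CGE.

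On chips 160 and above counts in progenitor-like cells were for MGE/CGE 2 at E12.5 and 1 at E14.5, for vMGE/dMGE 1 at E12.5 and 1 with age. Neuron-like cells had, in turn, for MGE/CGE 4 at E12.5 and 2 at E14.5 and 0 with age. The share of neuron-like cells gave 6.25 points for MGE/CGE at E14.5. Turned genes of progenitor-like cells were Prox1 -1.89, Npas3 -0.59, Dpysl2 -0.58 and Nmt2 -0.33 for MGE/CGE at E14.5, Nkx6-2 0 for vMGE/dMGE at E14.5, Cdc42bpb -2.78, Nfia -0.43, Mki67 -0.33, Mmd2 -4.24, Cdk6 -0.89, Cux2 -0.92, Zfp367 -0.86, Sp8 -2.74, Tubb3 -0.16, GPR45 -0.25 and AC113316.1 -1.09 with age and Dpysl2 -0.34 and Mn1 -0.17 for the age difference of MGE/CGE. Reversed genes in neuron-like cells were Dpysl2 -1.04 and GPR45 -0.15 for MGE/CGE at E14.5, Scgn 0 for vMGE/dMGE at E14.5, Crebl2 -0.81, Itga9 -0.775, Pou4f1 -2.51, Sp8 -1.41, Tubb3 -0.56, Unc5d -4.36 and Rn7sk -0.043 with age and Dpysl2 -0.69 for the age difference of MGE/CGE. Turned lists of progenitor-like cells had adjusted p = 0.102 (dissociation) for MGE/CGE at E14.5, 0.841 (pan-neuronal) for vMGE/dMGE at E14.5, 0.886 (late and gliogenic) and 0.394 (dissociation) with age and 0.628 (dissociation) for the age difference of MGE/CGE. For lists in neuron-like cells adjusted p was 0.907 (pan-neuronal), 0.894 (migration) and 0.49 (dissociation) with age and 0.73 (G2 and M phase) and 0.55 (pan-neuronal) for the age difference of MGE/CGE. Fewer chips enter here by construction.

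With all cells of a chip summed, 1 fit without classes, counts were for MGE/CGE 8 at E12.5 and 0 at E14.5 and 398 with age. Turned genes and lists are given against each class. Turned genes of progenitor-like cells were Htr3a -0.081 and Sp8 -1.71 for vMGE/dMGE at E12.5 and Npy 0.92 and Nr2f2 0.41 with age. Reversed genes in neuron-like cells were Scgn -0.56 for MGE/CGE at E12.5, Htr3a -0.081 for vMGE/dMGE at E12.5, St18 -0.61 for vMGE/dMGE at E14.5, Zfp641 0.56 with age and Rxra -4.54 for the age difference of vMGE/dMGE. List adjusted p in neuron-like cells was 0.243 (G2 and M phase), 0.835 (pan-neuronal) and 0.909 (erythroid) for the age difference of MGE/CGE. At clustering resolution 2 counts in progenitor-like cells were for MGE/CGE 19 at E14.5 and 1 in its age difference. Neuron-like cells had, in turn, for MGE/CGE 1 at E12.5 and 77 at E14.5. The share of neuron-like cells gave 22.9 points for E14.5 against E12.5 (past the threshold). Turned genes of progenitor-like cells were Htr3a -1.397 for vMGE/dMGE at E12.5 and Sox6 -0.26 for MGE/CGE at E14.5. Reversed genes in neuron-like cells were Calb2 0 for vMGE/dMGE at E12.5. List adjusted p in neuron-like cells was 0.757 (G2 and M phase) for MGE/CGE at E12.5.

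At clustering resolution 0.5 counts in progenitor-like cells were for MGE/CGE 2 at E12.5 and 1 at E14.5, for vMGE/dMGE 1 at E12.5 and 3 with age. Those of neuron-like cells were for MGE/CGE 5 at E12.5 and 2 at E14.5 and 0 with age. The neuron-like share gave 0.997 points for MGE/CGE at E14.5 and -2.48 points for vMGE/dMGE at E12.5. In progenitor-like cells signs turned for Prox1 -3.21, Dpysl2 -0.33, Nmt2 -0.61 and Ptp4a2 -0.65 for MGE/CGE at E14.5, Nkx6-2 0 for vMGE/dMGE at E14.5, Cdc42bpb -3.12, Nfia -0.61, Mki67 -0.18, Mmd2 -4.195, Cdk6 -0.75, Cux2 -0.76, Zfp367 -0.67, Sp8 -2.79, Tubb3 -0.25, GPR45 -1.26 and AC113316.1 -1.12 with age and Dpysl2 -0.16, Ptp4a2 -0.64 and Mn1 -0.48 for the age difference of MGE/CGE. Signs turned in neuron-like cells for Calb2 3.96 for MGE/CGE at E12.5, Dpysl2 -0.83 and GPR45 -0.34 for MGE/CGE at E14.5, Scgn 0 for vMGE/dMGE at E14.5, Zbtb20 -0.082, Itga9 -0.77, Pou4f1 -2.41, Sp8 -1.15, Tubb3 -0.42, Unc5d -4.58 and Rn7sk -0.59 with age and Dpysl2 -0.46 for the age difference of MGE/CGE. Turned lists of progenitor-like cells had adjusted p = 0.17 (dissociation) for MGE/CGE at E14.5, 0.783 (pan-neuronal) for vMGE/dMGE at E14.5, 0.812 (late and gliogenic) and 0.643 (dissociation) with age and 0.612 (dissociation) for the age difference of MGE/CGE. For lists in neuron-like cells adjusted p was 0.731 (late and gliogenic) and 0.244 (dissociation) with age and 0.783 (G2 and M phase) and 0.733 (pan-neuronal) for the age difference of MGE/CGE. Here a cluster of 626 cells, with Dpysl2, Cdk6, Ptp4a2 and GPR45 among its leading genes, stayed unnamed and its cells left the comparison.

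With clusters from scaled values counts in progenitor-like cells were for MGE/CGE 4 at E12.5, 257 at E14.5 and 17 in its age difference and 608 with age. The other class, neuron-like cells, had for MGE/CGE 0 at E12.5, 34 at E14.5 and 1 in its age difference, for vMGE/dMGE 1 at E14.5 and 0 with age. The neuron-like share gave 28.03 points for E14.5 against E12.5 (past the threshold), -21.4 points for MGE/CGE at E14.5 (past the threshold) and -8.98 points for vMGE/dMGE at E12.5. In progenitor-like cells signs turned for Sp8 -0.205 for vMGE/dMGE at E12.5, Nr2f2 0.36 for vMGE/dMGE at E14.5 and P2ry12 -1.64 for the age difference of vMGE/dMGE. Signs turned in neuron-like cells for Calb2 0 for MGE/CGE at E12.5, Calb2 0 for vMGE/dMGE at E12.5 and Scgn 2.61 with age. Turned lists of progenitor-like cells had adjusted p = 0.559 (microglia) for vMGE/dMGE at E14.5, 0.883 (radial glia) with age and 0.192 (microglia) for the age difference of vMGE/dMGE. For lists in neuron-like cells adjusted p was 0.803 (striatal) and 0.71 (dissociation) for vMGE/dMGE at E12.5 and 0.32 (pericyte) for the age difference of vMGE/dMGE.

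With clusters from values scaled within chips counts in progenitor-like cells were for MGE/CGE 3 at E12.5 and 8 at E14.5. Counts in neuron-like cells were for MGE/CGE 0 at E12.5 and 0 at E14.5. The share of neuron-like cells gave 4.01 points for MGE/CGE at E12.5 and -7.11 points for vMGE/dMGE at E12.5. Turned genes of progenitor-like cells were Htr3a -3.78 and Cux2 0.29 for vMGE/dMGE at E12.5, Npy -0.33 and Htr3a 0.61 for MGE/CGE at E14.5, Nr2f2 0.14 for vMGE/dMGE at E14.5 and Npy 0.33 with age. Reversed genes in neuron-like cells were St18 -0.25 for vMGE/dMGE at E14.5 and Rxra -4.08 and Rgs5 0.24 for the age difference of vMGE/dMGE. List adjusted p in progenitor-like cells was 0.924 (microglia) for vMGE/dMGE at E14.5 and 0.888 (microglia) for the age difference of vMGE/dMGE. With thinning before clustering the share of neuron-like cells gave 2.98 points for MGE/CGE at E12.5 and -16.8 points for vMGE/dMGE at E12.5. With clusters made without the called genes the share of neuron-like cells gave -12.2 points for vMGE/dMGE at E12.5. With 10 named cells per chip as the minimum the share of neuron-like cells gave -1.35 points for vMGE/dMGE at E12.5.

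Leaving out 1 chip at a time moved the E14.5 and age counts most. In progenitor-like cells the MGE/CGE count ran from 1 to 1 at E12.5 and from 2 to 244 at E14.5, and the age count from 144 to 560. Its highest values came without chip 193, and chip 194 gave 207 and 525. In neuron-like cells the ranges were 2 to 3 at E12.5, 0 to 405 at E14.5 and 162 to 719 with age, highest without chip 193, while chip 194 gave 281 and 707. The age difference of MGE/CGE ran from 0 to 35 in progenitor-like and 0 to 86 in neuron-like cells, again highest without chip 193. For vMGE/dMGE every fit gave 0 at E12.5 and in the age difference in both classes, and 0 at E14.5 in progenitor-like cells. In neuron-like cells at E14.5 it ran from 0 to 1. The neuron-like share ran from 7.80 to 12.6 points with age, from -17.9 to -7.50 for MGE/CGE at E12.5 and from -18.7 to -6.09 at E14.5, and for vMGE/dMGE from -1.35 to 13.6 at E12.5 and from -18.1 to -8.01 at E14.5. The E12.5 value of vMGE/dMGE changed sign without dMGE chip 181. Of gene values 5 changed sign or fell to 0 without 1 chip. In progenitor-like cells at E14.5 Htr3a ran from -3.92 to 7.19 (highest without CGE chip 160) and Nkx6-2 from -9.603 to 2.69 (the same chip) for MGE/CGE, and Nkx6-2 from -5.73 to 0 (without dMGE chip 101) for vMGE/dMGE. In neuron-like cells at E12.5 Calb2 ran from -8.31 to 3.79 (highest without CGE chip 172) for MGE/CGE and from 0 (without vMGE chip 185) to 7.91 for vMGE/dMGE.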

Other observations

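An alternative added after the data were seen gave each cell the same weight, with limma on the mean of log2(CPM + 1) over the cells of a chip. For MGE against CGE at E12.5 it called 21 genes in progenitor-like cells, 5 higher and 16 lower in MGE, and 45 in neuron-like cells, 28 higher and 17 lower. For vMGE against dMGE at E12.5 it called 3 genes in neuron-like cells. Of the genes named here, chosen after their values were seen, edgeR called only Nkx2-1 in neuron-like cells. In neuron-like cells Nkx2-1 had a mean log2 difference of 5.55 ± 0.51, Lhx6 5.17, Mbip 3.78 and the retinoic acid binding protein gene Crabp2 3.35, at 208 ± 76.6 CPM in MGE against 32.4 ± 20.2 in CGE. The neurogenic genes Insm1 and Dll3 were higher in MGE, at 138 against 68.4 CPM and 87.7 against 39.2. Lower in MGE were Nr2f2 at -3.09, Meis2 at -2.87, the growth cone gene Gap43 at -2.49, the MGE peptide gene Sst at -1.78, Foxp2 at -1.63 and Wnt5a at -1.02. Progenitor-like cells showed Nkx2-1 at 5.56, Mbip at 4.03, Lhx6 at 3.81 and Crabp2 at 2.84, and lower values of Nr2f2 at -3.28, Epha5 at -2.42, Pax6 at -2.25 and the Hedgehog effector Gli2 at -1.03. The vMGE genes of neuron-like cells, none called by edgeR, were Lhx8 at 3.20, Zic1 at 2.01 and Eya1 at 0.71.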
